A study of Mus musculus with 4 samples.

How the data were processed

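Single-cell RNA sequencing on the BD Rhapsody system had been run on group 3 innate lymphoid cells (ILC3s) sorted from the small-intestinal lamina propria of Cxxc1flox/flox mice with a cre transgene, aged 6 to 8 weeks. The 4 samples in the labels are 2 replicates with 2 sequencing libraries each. Both libraries of a replicate share a single table and 1 sample tag, so the number of replicates was 2. Replicate 1 was sample tag 4 of one capture and replicate 2 was sample tag 2 of another capture. The labels do not say that the replicates are separate animals. The p-values therefore measure only how far differences between classes of cells disagree between these 2 replicates, and that spread may be technical. All samples belong to 1 group, so no comparison with Cxxc1-sufficient cells was made here.

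The deposited tables hold counts of molecules (unique molecular identifiers, UMIs) per cell and gene, not normalised. Per the file headers, the counts came from the BD WTA Multiplex Rhapsody pipeline, version 1.8, with a GRCm38 reference and GENCODE vM19 genes. The sample tag of each cell is, per the file headers, a call of the same pipeline, and its unit is a name (other than a count). The submitters' processing notes also name HISAT2 2.0.5 and Bowtie2 without a role. The count values were checked to be whole numbers of at least 0 in the cells used. The captures held 8064 and 15793 cells, of which 2077 and 4532 carried the tags used, while 6 other sample tags, 349 and 572 multiplet calls and 508 and 1128 undetermined calls were not used. The tagged cells held 11939862 and 12141164 UMIs, with medians of 4027 and 2269 per cell. The 21027 genes present in both tables were kept, and the genes left out held 0.0343% and 0.0105% of the UMIs.

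Cells with at least 300 detected genes and at most 25% mitochondrial UMIs were kept, which left 1945 and 4185 cells. Scrublet, in scanpy 1.11.5, was run on each replicate and removed 41 cells (2.11%) and 5 cells (0.119%), so in replicate 2 it removed almost nothing and doublets must be taken as present. The 1904 and 4180 remaining cells were scaled to 10000 UMIs, log-transformed and scaled within each replicate. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2) at resolution 0.8, and gave 20 clusters. Each cluster was named from marker lists fixed before the data were examined, as were the gene lists, the gates, the tests and the rule for named genes. A marker counted as raised at 2-fold or more over the median of the clusters with a UMI in at least 10% of cells, and a name needed 3 raised markers. That median was chosen as the reference after the clusters had been seen. A cluster stayed unnamed when its top 10 genes held at least 2 markers of another class and more of them than of its own, or when its depth was low and none of its own markers was among those genes. ILC3-like cells were 3 clusters. Cluster 2 kept the name through its top 10 genes. These held 4 genes of the marker list of the NCR subset of ILC3s against 2 of the list of ILC1s or natural killer cells. Those 2 are on both lists, while Ncr1 and Klrk1 were put on the NCR subset list only. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

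ILC3-like cells were split by 2 gate genes. Ncr1-gated cells had at least 1 Ncr1 UMI and no Ccr6 UMI, Ccr6-gated cells had the opposite, and a remainder had neither; cells with both were left out. UMIs were summed per replicate and class into 6 sums. The sums were fitted with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM normalization, filterByExpr and replicate as a block, which leaves 2 residual degrees of freedom. The fit adds 16.1 prior degrees of freedom shared across genes, so small p-values rest mainly on spread borrowed from other genes. The test was two-sided, and p-values were adjusted by Benjamini-Hochberg over 7110 genes with a threshold of 0.05. The common biological coefficient of variation was 0.0740. The fit was tested on simulated data with 200 changed genes, each with a mean of at least 50 CPM. It recovered 69% of 2-fold and 99% of 4-fold changes, and 4 of 172 calls (2.33%) were false. Counts were drawn independently for each gene at the fitted spread, without a replicate effect. Recovery at lower levels was not measured, and the false share is a best case. The gate genes are not results. Gene lists were tested by camera (limma 3.58.1) with a preset correlation of 0.01, again with an estimated correlation, and by fry, each adjusted over the lists with at least 3 tested members. Unlike camera, fry does not compare a list with other genes but tests whether its members move on balance one way. Log2 fold changes are Ncr1-gated over Ccr6-gated with an approximate standard error (SE). The SE was back-calculated as the absolute log2 fold change divided by the square root of the F statistic of the test. Levels are CPM (UMIs of a gene scaled to the same total of UMIs in every class), given as means with the standard deviation (SD) of 2 replicates. The named genes were Cxxc1 and Klf4, the 12 largest changes in each direction past the threshold with at least 50 CPM in the higher class and the same sign in both replicates, and per list up to 4 members past the threshold by p and up to 2 not past it by level. Not every gene that the rule picked is named in the text. Genes with provisional or clone names were passed over, and 6 genes outside that rule, named below as such, were chosen after their values were seen.

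Shares of cells carry exact Clopper-Pearson 95% intervals and CPM of summed counts exact Poisson 95% intervals; both cover counting error only. Beside a share of 0, the limit given is 3 counts of the total. To compare shares at equal depth, each cell was thinned to 1895 UMIs, the 10th percentile of the gated cells, and shallower cells were left out. The gates were set before thinning for the effector shares and for the check of the type 1 and cytotoxic genes. In the alternative that repeated the gene comparison and the gate shares, they were set again on the thinned counts. The lists covered type 3 cytokines, type 1 and cytotoxic genes, lymphoid tissue inducer genes, MHC class II, H3K4 methyltransferases and demethylases, Kruppel-like factors, lineage transcription factors, homing, cytokine receptors, cell cycle (S; G2 and M), survival, immediate early genes, interferon response, glycolysis, oxidative phosphorylation, checkpoint receptors, T cell receptor and CD3 genes, and markers of ILC2s, B and plasma cells, myeloid and mast cells, and epithelium, stroma and endothelium. Alternatives changed the resolution, doublet removal, the cell filter, the ILC3-like restriction, the CCR6 gate, the depth, the block, the normalization, the low-count filter, the classes fitted and the tool (DESeq2 1.42.0). Cells with a CD3 or TCR UMI were those with a UMI of Cd3d, Cd3e, Cd3g, Trac, Trbc1 or Trbc2. UMIs of Trdc and the Tcrg genes did not count for this. Gene positions are from GENCODE vM21 (GRCm38).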

Results

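The series concerns how Cxxc1, a CXXC-domain subunit of the SET1 H3K4 methyltransferase complex, bears on intestinal ILC3s, innate lymphocytes of the gut mucosa that make IL-22. Sorted small-intestinal ILC3s of Cxxc1flox/flox mice with a cre transgene were measured in 2 replicates. Replicate 1 gave 2077 tagged cells with 11939862 UMIs and replicate 2 gave 4532 cells with 12141164 UMIs. After filtering, 1904 and 4180 cells remained, with medians of 4202.5 and 2364 UMIs per cell.

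Cxxc1 (ENSMUSG00000024560.7, chromosome 18, 74216124 to 74221496, GRCm38) was the targeted gene. In ILC3-like cells its transcript stood at 44.0 CPM (95% interval 35.5 to 54.1, 91 UMIs) in replicate 1 and 48.0 CPM (42.0 to 54.6, 230 UMIs) in replicate 2. T cell-like cells had 83.6 CPM (41.7 to 149.6) and 79.2 CPM (69.7 to 89.7) of Cxxc1. Stromal cell-like cells, which are not lymphocytes, had 67.8 CPM (58.6 to 78.2) and 55.2 CPM (45.2 to 66.8). Plasma cell-like cells had 73.0 CPM (65.1 to 81.6) and 37.8 CPM (21.2 to 62.4), dendritic cell-like cells 36.3 CPM (23.9 to 52.8) and 72.5 CPM (37.5 to 127), and macrophage or monocyte-like cells 49.0 CPM (28.0 to 79.5) and 56.0 CPM (32.0 to 90.9). The assay counts 3' ends of transcripts, so a UMI need not come from the deleted part of Cxxc1. These counts therefore do not check the deletion, and no Cxxc1-sufficient sample was used here.

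ILC3-like cells, named from raised markers such as Il23r, Il22, Il1r1 and Kit, made up 578 of 1904 cells (30.4%, 28.3 to 32.5) in replicate 1 and 1703 of 4180 cells (40.7%, 39.2 to 42.2) in replicate 2. Without cluster 2 (42 and 700 cells), whose top genes included Gzmc, Xcl1, Ncr1 and Klrb1c, the shares were 28.2% (26.1 to 30.2) and 24.0% (22.7 to 25.3), an alternative chosen after seeing the data. That cluster raised 9 of 11 ILC3 markers, 8 NCR subset markers and 7 ILC1 or natural killer cell markers, and the last 2 lists overlap. Among the markers of ILC3s, its top 10 genes held those of the NCR subset only. Of these, 2 were also on the list of ILC1 or natural killer cell markers. Ncr1 and Klrk1 were not put on that list, so this count depends on how the lists were drawn. Klf4, a zinc-finger transcription factor (chromosome 4, 55527143 to 55532466), stood at 998 and 921 CPM in ILC3-like cells and at 220 and 286 CPM in T cell-like cells. The classes outside the ILC3-like clusters differed between the replicates. Plasma cell-like cells were 28.6% of replicate 1 and 1.72% of replicate 2, and stromal cell-like cells were 17.2% and 6.15%. T cell-like cells were 2.52% of replicate 1 and 36.8% of replicate 2, which leaves out 2 unnamed clusters that raised T cell markers: cluster 10 (8 of 11 markers, 10.8% of replicate 1 and 0 cells of replicate 2) and cluster 7 (7 of 11 markers, 0.263% and 5.31%). Also left out is the ILC2-like class, which was cluster 8 alone (1.94% and 4.40%) and raised 8 of 11 T cell markers too. The sort, the tag calls and depth can each set these shares.

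**Figure D1:**
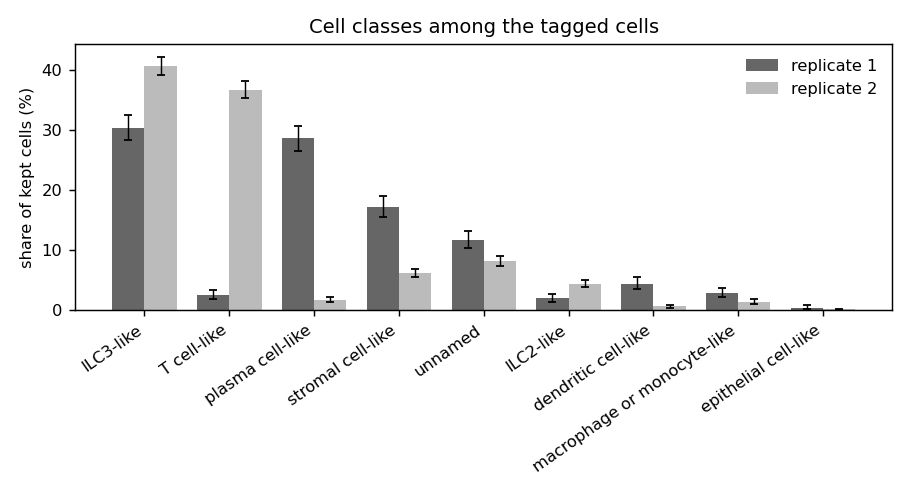
Share of kept cells (%) in each cell class, with bars for replicate 1 (1904 cells) and replicate 2 (4180 cells) and exact 95% intervals of counting error. ILC3-like cells, cluster 2 included, were 30.4% and 40.7%. The ILC2-like class was cluster 8, which also raised 8 of 11 T cell markers.

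The comparison within the ILC3-like cells set the NCR+ subset, which expresses the receptor NKp46 encoded by Ncr1, against the CCR6+ subset, which includes lymphoid tissue inducer-like cells. Ncr1-gated cells were 102 of the ILC3-like cells in replicate 1 (17.6%, 14.6 to 21.0) and 222 in replicate 2 (13.0%, 11.5 to 14.7). Ccr6-gated cells numbered 49 (8.48%, 6.34 to 11.1) and 160 (9.40%, 8.05 to 10.9). Without cluster 2 the Ncr1-gated shares were 16.0% (13.0 to 19.4) and 6.98% (5.48 to 8.74) and the Ccr6-gated shares 9.14% (6.84 to 11.9) and 15.5% (13.3 to 17.8). Without cells with a CD3 or TCR UMI the shares were 11.3% (7.91 to 15.5) and 10.03% (8.15 to 12.2) against 11.6% (8.20 to 15.9) and 11.5% (9.47 to 13.8), a difference not detectable at this depth. With the wider CCR6 gate, which also takes Nrp1 or Cd4, they were 16.3% and 11.5% against 18.7% and 19.4%, so the order of the 2 classes depended on these choices. Both shares depend on depth, since a cell with few UMIs can miss its gate gene. Median depth was 3208 and 2762.5 UMIs in Ncr1-gated cells and 3981 and 3399 in Ccr6-gated cells. Cluster 3 held 84.3% of Ncr1-gated and 87.8% of Ccr6-gated cells in replicate 1. In replicate 2, cluster 2 held 68.5% of Ncr1-gated cells, and cluster 1 held 90.6% of Ccr6-gated cells.

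With a preset correlation, the list of type 1 and cytotoxic genes was higher in Ncr1-gated cells, and those of type 3 cytokines and MHC class II in Ccr6-gated cells. None of these calls held with an estimated correlation (adjusted p = 0.206 each). Gzma, a granule protease, stood at 879 ± 507 CPM (SD, n = 2) in Ncr1-gated and 12.4 ± 17.6 CPM in Ccr6-gated cells (log2 fold change 5.34, SE 0.35, adjusted p = 9.5e-09). Xcl1, a chemokine that draws cross-presenting dendritic cells, stood at 940 ± 154 against 67.3 ± 55.0 CPM (log2 fold change 4.14, SE 0.23, adjusted p = 1.6e-09). In the other direction Cd74, the MHC class II invariant chain, stood at 302 ± 140 CPM in Ncr1-gated and 2358 ± 230 CPM in Ccr6-gated cells (log2 fold change -2.91, SE 0.18, adjusted p = 4.0e-09). Il17a, a cytokine of mucosal defence, stood at 3.74 ± 1.24 against 76.5 ± 39.9 CPM (log2 fold change -4.44, SE 0.70, adjusted p = 3.0e-04). By the edgeR test with the replicate block, 282 genes were higher in Ncr1-gated and 313 in Ccr6-gated cells. Those counts fell to 117 and 134 with DESeq2 and to 109 and 146 without cluster 2, an alternative chosen after seeing the data.

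**Figure D2:**
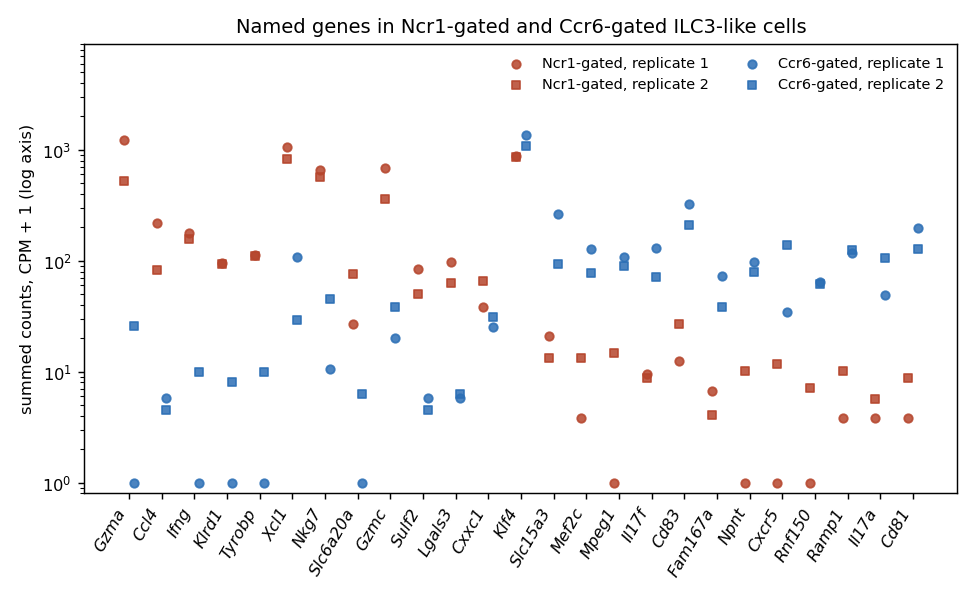
Summed counts (CPM + 1, log axis) of the named genes with the largest changes, and of Cxxc1 and Klf4, in Ncr1-gated and Ccr6-gated ILC3-like cells. Each point is 1 replicate; Gzma lay at 1237 and 520 CPM and Xcl1 at 1049 and 831 CPM in the Ncr1-gated class, and Cd83 at 324 and 209 CPM in the Ccr6-gated class.

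Of the 24 tested type 1 and cytotoxic genes, 20 were higher in Ncr1-gated cells, 1 was higher in Ccr6-gated cells and 3 did not pass. Adjusted over the list alone, 23 were higher in Ncr1-gated cells and 1 in Ccr6-gated cells. The list as a whole passed with the preset correlation (adjusted p = 1.3e-60), but adjusted p = 0.206 with an estimated correlation. Its median log2 fold change, computed per replicate, was 2.73 and 2.16, and without cluster 2 it was 2.58 and 0.67. The list is not independent of the cluster names. All NCR subset markers used in naming clusters, other than Ncr1, were on this list, among them Klrd1, Il12rb1, Gzmb, Xcl1 and Ifng. Cluster 2 kept its ILC3-like name through Ncr1, Xcl1, Klrb1c and Klrk1, and held 68.5% of the Ncr1-gated cells of replicate 2. Ifng, which encodes interferon-γ, had a log2 fold change of 4.59 (SE 0.45, adjusted p = 1.1e-06). Nkg7, a cytotoxic granule protein, had one of 4.14 (SE 0.25), Gzmc one of 3.93 (SE 0.36) and Gzmb one of 3.77 (SE 0.30). Klrd1, which encodes the receptor CD94, had a log2 fold change of 4.27 (SE 0.60). Ccl4, an inflammatory chemokine, had 129 UMIs in Ncr1-gated and 3 UMIs in Ccr6-gated cells, a ratio of 33.1 (counting interval 11.1 to 163). Il12rb1, a shared chain of the IL-12 and IL-23 receptors and chosen after its values were seen, was the member higher in Ccr6-gated cells (log2 fold change -1.25, SE 0.32). That call was lost with DESeq2, which called 18 members higher in Ncr1-gated and 0 in Ccr6-gated cells. Cd226 had 75.0 ± 9.14 against 29.7 ± 28.3 CPM and did not pass (adjusted p = 0.0584).

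Some T cell genes were also higher in Ncr1-gated cells. Of 11 tested T cell receptor and CD3 genes, 4 were higher in Ncr1-gated cells, 1 was higher in Ccr6-gated cells and 6 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.00233; adjusted p = 0.256 with an estimated correlation). The list call was also lost in cells thinned and gated again (adjusted p = 0.453) and with the wider CCR6 gate (adjusted p = 0.190). Trbc1 had a log2 fold change of 3.06 (SE 0.27), Tcrg-C4 of 2.09 (SE 0.36) and Trbc2 of 1.44 (SE 0.23). Trdc also rose, at 2.42 (SE 0.65), and was chosen after its values were seen. Tcrg-C1, a γ chain constant region, was the member higher in Ccr6-gated cells (log2 fold change -1.09, SE 0.13). No UMI of Cd3d, Cd3e, Cd3g, Trac, Trbc1 or Trbc2 was found in 33 of 102 Ncr1-gated and 34 of 49 Ccr6-gated cells of replicate 1. In replicate 2 these were 90 of 222 and 103 of 160 cells. Trdc and the Tcrg genes were not part of that filter. Of 4 tested myeloid and mast cell markers, Tyrobp and Ccr2 were higher in Ncr1-gated cells and 2 did not pass, while adjusted over the list alone 3 were higher (adjusted p = 1.5e-04; adjusted p = 0.253 with an estimated correlation). This list did not pass without cells with a CD3 or TCR UMI (adjusted p = 0.137) or with no low-count filter (adjusted p = 0.0882). Tyrobp encodes DAP12, an adaptor that natural killer cells also use, and had a log2 fold change of 4.15 (SE 0.50).

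Type 3 effector genes lay on the Ccr6-gated side. Of 11 tested type 3 cytokines and lymphotoxins, 8 were higher in Ccr6-gated cells, 1 in Ncr1-gated cells and 2 did not pass; adjusted over the list alone the counts were 9 and 1. The list passed with the preset correlation (adjusted p = 1.6e-11; adjusted p = 0.206 with an estimated correlation). Il22, a cytokine that acts on epithelium, stood at 4820 ± 1430 CPM in Ccr6-gated and 2007 ± 462 CPM in Ncr1-gated cells (log2 fold change -1.23, SE 0.16, adjusted p = 3.4e-05). Il17f had a log2 fold change of -3.49 (SE 0.42), and Tnfsf11, the gene of RANK ligand, one of -1.67 (SE 0.15). Furin, a proprotein convertase chosen after its values were seen, was the member higher in Ncr1-gated cells (log2 fold change 0.55, SE 0.15). With DESeq2 the Furin call was lost, and 6 members were higher in Ccr6-gated and 0 in Ncr1-gated cells. Ltb, a lymphotoxin chain, had 79.2 ± 27.2 against 71.2 ± 32.4 CPM and Lta 70.0 ± 14.2 against 96.5 ± 6.65 CPM, and neither passed.

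Lymphoid tissue inducer genes gave 9 members higher in Ccr6-gated cells, 1 in Ncr1-gated cells and 7 that did not pass of 17 tested. Adjusted over the list alone the counts were 10 and 1 (adjusted p = 4.1e-09; adjusted p = 0.253 with an estimated correlation). This list too shares genes with the cluster names. All CCR6 subset markers used in naming clusters, other than Ccr6, were on it, among them Cxcr5 and Nrp1. None of them was among the top 10 genes of an ILC3-like cluster. Cxcr5, a B cell follicle homing receptor, had a log2 fold change of -3.82 (SE 0.46) and Cd83 one of -3.57 (SE 0.34). Nrp1, the gene of neuropilin-1, had one of -2.31 (SE 0.37). Itgb3, an integrin chain chosen after its values were seen, was the exception (log2 fold change 0.72, SE 0.19). Its call was lost with DESeq2, which called 5 lymphoid tissue inducer genes higher in Ccr6-gated and 0 in Ncr1-gated cells. Among 9 tested MHC class II genes, 8 were higher in Ccr6-gated cells, 0 in Ncr1-gated cells and 1 did not pass, and adjusted over the list alone all 9 were higher (adjusted p = 2.0e-30; adjusted p = 0.206 with an estimated correlation). H2-Aa, H2-Ab1 and H2-Eb1, classical class II chains, had log2 fold changes of -2.74 (SE 0.20), -2.43 (SE 0.15) and -2.72 (SE 0.21). Ciita, the class II transactivator, had 3.74 ± 1.24 against 26.0 ± 4.17 CPM and did not pass (adjusted p = 0.05004). With DESeq2, 5 of the 9 MHC class II genes were called higher in Ccr6-gated cells. Of 7 tested B and plasma cell markers, Igha, Igkc, Jchain and Sdc1 were higher in Ccr6-gated cells and 3 did not pass, and adjusted over the list alone 4 were higher in Ccr6-gated and 1 in Ncr1-gated cells. Its list did not pass (adjusted p = 0.277; adjusted p = 0.601 with an estimated correlation), though it passed, lower in Ncr1-gated cells, without cluster 2 (adjusted p = 0.0052), in all filtered cells (adjusted p = 1.6e-04) and with 2 classes in the fit (adjusted p = 0.0282), and its mean (0.32) and median (-0.52) log2 fold change differed in sign. Igha had a log2 fold change of -0.56 (SE 0.11). It changed sign in cells thinned and gated again (0.11), as did that of Igkc (0.22) and Jchain (0.82). With DESeq2, 0 of the 7 B and plasma cell markers passed.

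The other genes with the largest changes were of mixed function. Higher in Ncr1-gated cells were Lgals3, a galectin (log2 fold change 3.82, SE 0.52), and, with 3 UMIs each in Ccr6-gated cells, Sulf2, an extracellular sulfatase, at a ratio of 15.7 (counting interval 5.11 to 78.1) and the transporter gene Slc6a20a at 14.9 (4.85 to 74.3). Higher in Ccr6-gated cells were the tetraspanin gene Cd81 (log2 fold change -4.62, SE 0.44), Ramp1, a subunit of the receptor for the neuropeptide CGRP (-4.09, SE 0.43), and Rnf150 (-3.90, SE 0.60). Npnt, an extracellular matrix gene, had -3.79 (SE 0.52), Fam167a -3.61 (SE 0.60) and Mpeg1, which encodes perforin-2, -3.38 (SE 0.50). Mef2c, a transcription factor, had -3.34 (SE 0.47) and Slc15a3, a lysosomal transporter gene, -3.30 (SE 0.47).

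**Figure D3:**
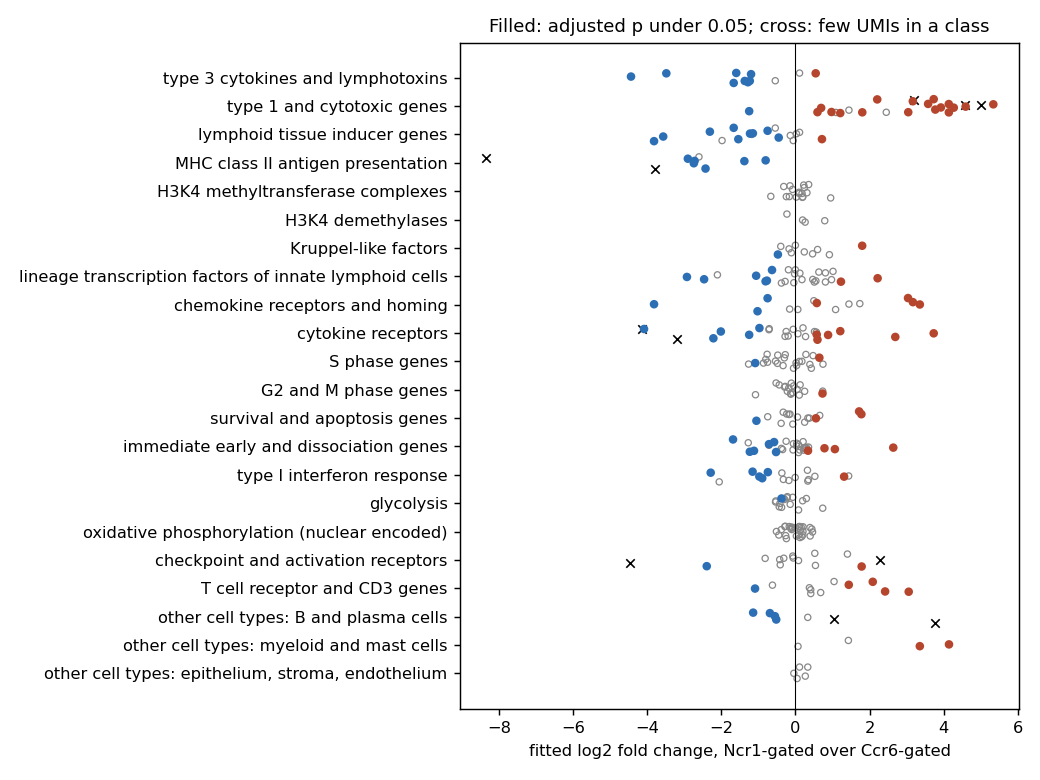
Fitted log2 fold change (Ncr1-gated over Ccr6-gated) of each tested member of the fixed gene lists. Filled points passed an adjusted p of 0.05, open points did not, and crosses mark members with at most 3 UMIs in a class, whose fitted value depends on the prior count; 20 of 24 type 1 and cytotoxic genes lay above 0 and passed.

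Of 17 tested H3K4 methyltransferase complex genes 0 passed in edgeR and 0 in DESeq2, and 0 adjusted over the list alone. The list did not pass (list adjusted p = 0.713, and adjusted p = 0.865 with an estimated correlation). In edgeR 1 member had an unadjusted p under 0.05, and that member was Cxxc1. Cxxc1 had 50.9 ± 19.4 CPM in Ncr1-gated and 27.2 ± 4.26 CPM in Ccr6-gated cells (log2 fold change 0.95, SE 0.37, adjusted p = 0.141). It was higher in Ncr1-gated cells in each replicate (37.1 against 24.1 and 64.6 against 30.2 CPM). The difference did not pass the threshold and rests on 5 and 17 UMIs in Ccr6-gated cells. Kmt2a had 278 ± 59.9 against 233 ± 8.93 CPM and Kmt2c 186 ± 24.3 against 177 ± 3.82 CPM, and both encode H3K4 methyltransferases. All 4 tested H3K4 demethylase genes did not pass in edgeR or DESeq2, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.683; adjusted p = 0.787 with an estimated correlation; 0 adjusted over the list alone). Kdm5a, among them, had 147 ± 54.1 against 117 ± 8.05 CPM. Of 10 tested Kruppel-like factors, Klf2 was higher in Ncr1-gated cells (adjusted p = 1.8e-06), Klf4 was higher in Ccr6-gated cells and 8 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.371; adjusted p = 0.715 with an estimated correlation). Klf4 stood at 866 ± 11.5 CPM in Ncr1-gated and 1224 ± 188 CPM in Ccr6-gated cells (log2 fold change -0.47, SE 0.10, adjusted p = 0.0051), and this call was lost with DESeq2 (log2 fold change -0.49). Klf6 had 1225 ± 262 against 1421 ± 245 CPM.

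Lineage transcription factors split. Of 25 tested, 6 were higher in Ccr6-gated cells, 2 in Ncr1-gated cells and 17 did not pass, and adjusted over the list alone the counts were 8 and 5 (list adjusted p = 0.547; adjusted p = 0.715 with an estimated correlation). Tcf7, which encodes TCF-1, had a log2 fold change of -0.77 (SE 0.11) and Tox2 of -2.93 (SE 0.39). Ikzf2 and Ikzf3, Ikaros family genes, were higher in Ncr1-gated cells, at 1.23 (SE 0.17) and 2.22 (SE 0.32); Ikzf3 was chosen after its values were seen. Rora had 2575 ± 8.30 against 2367 ± 39.6 CPM and Id2 923 ± 214 against 945 ± 180 CPM. Of 13 tested homing genes, 4 were higher in Ncr1-gated cells, 3 in Ccr6-gated cells and 6 did not pass, with 6 and 3 adjusted over the list alone (list adjusted p = 0.0514; adjusted p = 0.359 with an estimated correlation). The list passed, higher in Ncr1-gated cells, without the replicate block (adjusted p = 0.00529) and without cells with a Y-linked UMI (adjusted p = 0.0182). Ccr9, the small intestine homing receptor, had a log2 fold change of 3.04 (SE 0.30), Itga1, a collagen-binding integrin chain, of 3.17 (SE 0.50) and Ccr2 of 3.36 (SE 0.53). Cytokine receptors gave 6 members higher in Ncr1-gated cells, 7 in Ccr6-gated cells and 11 that did not pass of 24 tested, with 6 and 9 adjusted over the list alone (list adjusted p = 0.627; adjusted p = 0.715 with an estimated correlation). In all filtered cells this list passed, lower in Ncr1-gated cells (adjusted p = 0.0227). DESeq2 called 3 cytokine receptors higher in Ncr1-gated and 4 in Ccr6-gated cells. For lineage transcription factors it called 2 and 3. Il12rb2 (log2 fold change 3.73, SE 0.30) lay on the Ncr1-gated side, and the IL-1 receptor gene Il1r1 (-2.01, SE 0.18) and Il17re (-2.22, SE 0.35) on the Ccr6-gated side.

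Type I interferon response genes gave 5 members higher in Ccr6-gated cells, 1 in Ncr1-gated cells and 10 that did not pass of 16 tested, with 6 and 1 adjusted over the list alone (list adjusted p = 0.0308; adjusted p = 0.344 with an estimated correlation). The list call was also lost without cluster 2 (adjusted p = 0.293), without the replicate block (adjusted p = 0.0829), in all filtered cells (adjusted p = 0.0865) and with no low-count filter (adjusted p = 0.124). The interferon-inducible GTPase genes Iigp1 and Igtp had log2 fold changes of -2.29 (SE 0.26) and -1.16 (SE 0.15), and Ifi47, of the same family, had -0.98 (SE 0.18). Irf7, chosen after its values were seen, had 1.31 (SE 0.26). Of 29 tested immediate early and dissociation genes, 6 were higher in Ccr6-gated cells, 4 in Ncr1-gated cells and 19 did not pass, with 8 and 7 adjusted over the list alone (list adjusted p = 0.683; adjusted p = 0.865 with an estimated correlation). Its median (0.03) and mean (-0.07) log2 fold change differed in sign. Atf3 (-1.23, SE 0.12), Egr1 (-1.12, SE 0.13) and Zfp36 (-0.72, SE 0.09) lay on the Ccr6-gated side and Dusp1 (0.78, SE 0.10) on the Ncr1-gated side. These genes also respond to tissue digestion.

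**Figure D4:**
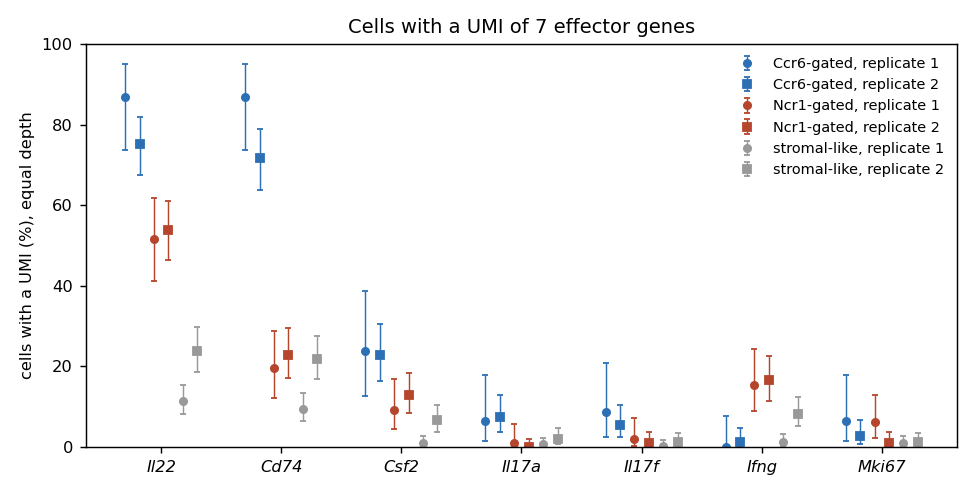
Share of cells with a UMI (%) of 7 effector genes in Ccr6-gated, Ncr1-gated and stromal cell-like cells, each cell thinned to 1895 UMIs, by replicate and with exact 95% intervals. Il22 was found in 87.0% and 75.2% of Ccr6-gated cells and in 51.5% and 53.7% of Ncr1-gated cells.

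At equal depth, Il22 was found in 87.0% (73.7 to 95.1) and 75.2% (67.4 to 81.9) of Ccr6-gated cells and in 51.5% (41.2 to 61.8) and 53.7% (46.3 to 61.0) of Ncr1-gated cells. Stromal cell-like cells, which should lack it, gave 11.4% and 23.9%, and plasma cell-like cells gave 22.3% and 32.1%. Before thinning the Il22 shares were 93.9% and 80.6% of Ccr6-gated cells, 59.8% and 53.2% of Ncr1-gated cells and 37.0% and 44.0% of stromal cell-like cells, whose median depths were 8542 and 7061 UMIs. Cd74 was found in 87.0% and 71.8% of Ccr6-gated cells, 19.6% and 22.9% of Ncr1-gated cells and 9.52% and 21.8% of stromal cell-like cells. T cell-like cells gave Cd74 in 18.2% and 8.35%. Csf2, which encodes GM-CSF, was found in 23.9% and 22.8% of Ccr6-gated cells, 9.28% and 12.8% of Ncr1-gated cells and 0.952% and 6.58% of stromal cell-like cells. Ifng was found in 15.5% and 16.5% of Ncr1-gated cells, 1.27% and 8.23% of stromal cell-like cells, 0.986% and 13.2% (5.48 to 25.3) of plasma cell-like cells, 30.3% and 38.6% of T cell-like cells and 1.34% of Ccr6-gated cells of replicate 2. In replicate 1, 0 of 46 Ccr6-gated cells had an Ifng UMI, which allows a share of cells with a UMI of up to 6.52%.

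Il17a was found in 6.52% and 7.38% of Ccr6-gated cells, 1.03% of Ncr1-gated cells of replicate 1 and 0.635% and 2.06% of stromal cell-like cells. In replicate 2, 0 of 188 Ncr1-gated cells had an Il17a UMI, which allows a share of cells with a UMI of up to 1.60%. Il17f was found in 8.70% and 5.37% of Ccr6-gated and 2.06% and 1.06% of Ncr1-gated cells, against 0.317% and 1.23% of stromal cell-like cells. Mki67, a proliferation marker, was found in 6.52% and 2.68% of Ccr6-gated and 6.19% and 1.06% of Ncr1-gated cells, so no difference was detectable at this depth. Before thinning, replicates 1 and 2 gave Cd74 in 89.8% and 77.5% of Ccr6-gated and 26.5% and 27.9% of Ncr1-gated cells, and Csf2 in 34.7% and 28.1% against 14.7% and 15.8%. Ifng was then found in 0% and 3.13% of Ccr6-gated and 27.5% and 23.0% of Ncr1-gated cells, Il17a in 12.2% and 8.75% against 0.980% and 1.35%, Il17f in 20.4% and 11.9% against 2.94% and 1.802%, and Mki67 in 8.16% and 3.75% against 9.80% and 1.802%. Stromal cell-like cells then gave 26.0% and 43.6% for Cd74, 2.75% and 12.5% for Csf2, 2.14% and 19.5% for Ifng, 2.14% and 4.28% for Il17a, 2.14% and 1.95% for Il17f, and 3.36% and 3.50% for Mki67. Thinning left out 5 and 34 Ncr1-gated cells and 3 and 11 Ccr6-gated cells. No test was made on shares, since no exact permutation test of 2 replicates against 2 can pass.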

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

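The use of each test below was chosen after the results had been seen, although the stricter cell filter and the thinning were planned as alternatives. The reference cells of the doublet and male-cell tests of the Y-linked genes were changed after their values were seen, and both went from arguing against the explanation to leaving it open. The tests of the type 1 and cytotoxic genes were made stricter after their values were seen, by asking that the whole interval lie above the bound.

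Y-linked genes (Ddx3y, Eif2s3y, Uty and Kdm5d), which no comparison used, had UMIs in 55.2% (42.6 to 67.4) of the 67 replicate 2 cells of ILC3-like cluster 3. Only 2 Y-linked UMIs were found in the 1904 cells of replicate 1, against 337 in the 4180 cells of replicate 2. At equal depth the share in cluster 3 was 35.9% (24.3 to 48.9) against 3.49% (2.56 to 4.64) in the other ILC3-like cells of replicate 2, which argues against free RNA, since that gives all types a like share. Doublets of female and male cells stay open: cells with a Y-linked UMI had 0.978 times the median UMIs of the cluster's other cells (0.749 to 1.35) but 1.505 times those of the other ILC3-like cells (1.22 to 1.84). Male cells in the tagged sample stay open too, since Xist was found in 54.1% (36.9 to 70.5) of the cells with a Y-linked UMI, an interval that spans the bound of 43.8%, and no biological explanation was tested.

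Type 1 and cytotoxic genes were higher in Ncr1-gated ILC3-like cells, with a median log2 fold change over the 24 members of 2.73 in replicate 1 and 2.16 in replicate 2, computed per replicate with a prior of 5 CPM. Doublets with T cells would lower that median among cells with no CD3 or TCR UMI, but it was 2.85 and 2.57. Cells with a UMI of Trdc or a Tcrg gene can stay in that set. Cells thinned to equal depth gave 2.90 and 2.00. These values cannot decide on the depth gap, since the gates were set before thinning and thinning hardly changes CPM. The bound, 0.5 times the value over all gated cells, was 1.37 in replicate 1 and 1.08 in replicate 2. The intervals of the cells with no CD3 or TCR UMI began at 2.25 and 1.59. The top 10 genes of cluster 2 held 2 genes of the list of ILC1 or natural killer cell markers, both also on the NCR subset list. Ncr1 and Klrk1 were put on the NCR subset list only. Outside cluster 2 the median was 2.58 (1.93 to 3.27) in replicate 1 but 0.67 (0.20 to 1.06) in replicate 2, under the bound there. Leaving out cluster 2 takes out cells high in type 1 and cytotoxic genes whatever their type. Replicate 1 hardly tests the point, since cluster 3 held 84.3% of its Ncr1-gated cells. Cluster 3 also raised 6 ILC1 or natural killer cell markers. ILC1 or natural killer cells of cluster 2 therefore stay open as a cause. Cells of other lineages in the other ILC3-like clusters were not analysed here, and no biological explanation was tested, since all samples belong to 1 group.

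Cells outside the ILC3-like clusters were 69.6% of replicate 1 and 59.3% of replicate 2, although the labels describe sorted ILC3s. Whether the cluster names missed ILC3s was not analysed here. Low-quality cells are argued against, since a stricter cell filter left 67.2% and 56.0% of cells outside the ILC3-like clusters. Cells of other samples that carried a wrong tag were not tested, because the other tags are not used here, and no biological explanation was tested.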

How the results depend on the processing

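The alternatives without cluster 2, without cells with a CD3 or TCR UMI and without cells with a Y-linked UMI, those for the effector shares and the wider CCR6 gate for the gate shares were chosen after seeing the data. The counts of 282 genes higher in Ncr1-gated and 313 in Ccr6-gated cells stayed within 1.5 times with both other Leiden resolutions, no doublet removal, the stricter cell filter, the wider CCR6 gate, DESeq2 size factors, no TMM, no low-count filter, 2 classes in the fit and no Y-positive cells. With the wider CCR6 gate, Nrp1 and Cd4 also set the classes but were not left out of the tests or lists. Their values there are fixed by the gate and are not results. All 251 genes that DESeq2 called (117 and 134) were among the 595. In the same order, it called 3 and 1 T cell receptor and CD3 genes, 3 and 2 homing genes and 2 and 1 survival genes. For immediate early genes it called 3 and 5, and for interferon response genes 1 and 4. Without the replicate block the counts of genes were 128 and 148. Thinned cells, gated again on the thinned counts, gave 129 and 138, with 4200 genes tested. This left 71 and 141 Ncr1-gated and 20 and 88 Ccr6-gated cells, so depth was not the only change. Leaving out cluster 2 gave 109 and 146, and leaving out cells with a CD3 or TCR UMI gave 147 and 183. All filtered cells, whatever their cluster, gave 4 and 13. The number of lists past the threshold was 7, and 5 to 9 in the alternatives except for camera with an estimated correlation, which gave 0, and fry, which gave 0 (smallest adjusted p = 0.0514); camera was not run with DESeq2. Leaving out a replicate leaves no residual degrees of freedom and so no test.

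The mean share of Ncr1-gated cells was 15.3%, but 5.91% of all filtered cells and 11.7% of thinned cells, and that of Ccr6-gated cells was 8.94%, but 3.93% and 5.07%. Without cluster 2 these means were 11.5% and 12.3%, and without cells with a CD3 or TCR UMI 10.7% and 11.6%. With the wider CCR6 gate the Ccr6-gated mean was 19.1%. The mean ILC3-like share was 35.5%, but 26.1% without cluster 2 and 50.6% without cells with a CD3 or TCR UMI, which also left the total (26.9% in replicate 1 and 74.3% in replicate 2). Cxxc1 stood at 46.0 CPM in ILC3-like cells, at 62.2 CPM in all filtered cells and at 42.7 CPM without CD3- or TCR-positive cells. The ILC3-like share was not recomputed over all filtered cells, where it has no meaning. Depth limits the gates, since a cell with few UMIs can miss its gate gene. The cause of the other changes was not tested.

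Of the 86 named genes with alternatives, values changed sign 15 times. In cells thinned and gated again the log2 fold change was 0.081 for Id2, 0.11 for Igha and 0.22 for Igkc. There it was 0.82 for Jchain, -0.19 for Kmt2a and -0.76 for Ltb. Without CD3- or TCR-positive cells it was 0.046 for Id2, 0.31 for Jchain, -0.12 for Kdm5a and -0.011 for Ltb. In all filtered cells Id2 had 0.12 and Ltb -0.17. With the wider CCR6 gate Id2 had 0.065, without cluster 2 Lta had 0.051, and with no doublet removal Igkc had 0.63. The call was lost 155 times, of which 68 were in all filtered cells, and gained 8 times, and 1181 values kept direction and call. Leaving out replicate 1 or 2 moved 25 and 18 values by more than 1 SD, which measures no stability: either of 2 replicates lies within 1 SD of their mean, and the values of 1 replicate used another prior count than the fit.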

Other observations

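Of 23 tested S phase genes, Pcna was higher in Ncr1-gated cells (log2 fold change 0.64, SE 0.18), Rrm1 was higher in Ccr6-gated cells (-1.09, SE 0.31) and 21 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.713; adjusted p = 0.865 with an estimated correlation). Of 18 tested G2 and M phase genes, Hmgb2 was higher in Ncr1-gated cells (0.71, SE 0.15) and 17 did not pass, also adjusted over the list alone (list adjusted p = 0.995; adjusted p = 0.996 with an estimated correlation). Survival and apoptosis genes gave 3 members higher in Ncr1-gated cells, 1 in Ccr6-gated cells and 12 that did not pass, the same adjusted over the list alone (list adjusted p = 0.827; adjusted p = 0.865 with an estimated correlation), with a median of -0.01 and a mean of 0.16. Bcl2l11, a pro-apoptotic gene, had a log2 fold change of 1.72 (SE 0.28), and Bcl2, which opposes apoptosis, had -1.05 (SE 0.13). Bcl2a1d (1.78, SE 0.31) and Birc2 (0.55, SE 0.16) were the others. Hexokinase gene Hk2 was the 1 of 16 glycolysis genes that passed, higher in Ccr6-gated cells (-0.38, SE 0.10), also adjusted over the list alone. The glycolysis list did not pass (list adjusted p = 0.235, and adjusted p = 0.529 with an estimated correlation). With DESeq2, 0 S phase, 0 G2 and M phase and 0 glycolysis genes passed. The calls of Pcna, Rrm1, Hmgb2 and Hk2 were thus lost there.

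Of 28 oxidative phosphorylation genes 0 passed in edgeR, 0 in DESeq2 and 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05 (list adjusted p = 0.995; adjusted p = 0.996 with an estimated correlation), and camera put the list higher in Ncr1-gated cells while fry put it lower. Checkpoint and activation receptors gave 1 member higher in Ncr1-gated cells, 2 in Ccr6-gated cells and 11 that did not pass, with 2 and 2 adjusted over the list alone (list adjusted p = 0.371; adjusted p = 0.715 with an estimated correlation). The list passed, lower in Ncr1-gated cells, without cells with a CD3 or TCR UMI (adjusted p = 0.0316) and with 2 classes in the fit (adjusted p = 0.0463). Tnfrsf18, which encodes GITR, had a log2 fold change of 1.79 (SE 0.27) and Ly6a, which encodes Sca-1, -2.40 (SE 0.18). Pdcd1, which encodes PD-1, had 36 UMIs in Ccr6-gated and 2 in Ncr1-gated cells, a ratio of 23.4 (counting interval 6.01 to 200.3). Among ILC2 markers only Areg was tested and was higher in Ccr6-gated cells (log2 fold change -1.28, SE 0.29), also adjusted over the list alone. The Areg call was lost with DESeq2, which called 0 ILC2 markers. Of 5 tested epithelial, stromal and endothelial markers 0 passed in edgeR, 0 in DESeq2 and 0 adjusted over the list alone. Of these markers 0 had an unadjusted p under 0.05 (list adjusted p = 0.713, and adjusted p = 0.865 with an estimated correlation).

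Cluster 8, the ILC2-like class, had 37 cells (1.94%) in replicate 1 and 184 cells (4.40%) in replicate 2. It raised 8 of 11 ILC2 markers and 8 of 11 T cell markers, so its name does not tell the 2 types apart. Cd3e, a CD3 chain, had a UMI in 78.4% and 77.2% of its cells. Its Cxxc1 level was 108 CPM (57.6 to 184.9) in replicate 1 and 73.0 CPM (51.1 to 101) in replicate 2. Klf4 stood at 1347 and 1412 CPM in stromal cell-like cells and at 925 and 917 CPM in macrophage or monocyte-like cells. Unnamed clusters held 11.7% and 8.11% of cells, led by Trdc, Cd8a and Gzma in one and by Ifng, Gzmk and Cd28 in another.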
